A study of Mus musculus with 6 samples.

How the data were processed

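RNA was measured in the neocortex of 6 mouse embryos at embryonic day 15.5, 3 wild type (WT) and 3 heterozygous for a Rest allele that lacks exon 4 (Rest_het). The genotype in the labels set the group of each library, and the number in the title set the replicate. The strain is given as C57BL/6 for all samples. The labels state no sex, litter or preparation batch. They name separate mice, without saying whether these shared a litter.

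Per the labels' protocols, cDNA was primed with oligo dT, extended with a template-switching oligo and amplified for 12 PCR cycles. Then 125 pg of it was tagmented with Nextera XT and sequenced as paired reads of 126 bases. This chemistry does not mark strand and holds no molecular identifiers, so PCR copies were counted as reads. Reads of a gene and of an overlapping antisense gene cannot be told apart.

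The deposited per-sample files hold whole-number read counts per gene, made by the authors with STAR 2.5.2a on GRCm38.p4, per the submitters' processing notes. The unstranded column was used. The 2 strand columns held nearly equal shares, with 49.9 to 50.1% on the forward strand. Rows that name no gene stayed out of library sizes and tests: 1.21 to 1.45% of all read pairs were unmapped, 6.29 to 7.48% mapped to several places, 21.4 to 26.9% fell in no annotated gene and 2.54 to 2.85% were ambiguous between genes. The files also list 92 spike-in sequences and 15 transgene sequences, which were kept out of the gene tests. The second kind of file is a deposited table of normalized signal per gene, made with DESeq2 per the submitters' processing notes, which give no version. It holds 18995 genes. Each nonzero value equalled the read count divided by 1 size factor per library, to a relative tolerance of 1e-06.

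Gene symbols were matched for 48349 of 48709 gene IDs, and positions came from the GENCODE annotation of GRCm38. Gene reads per library ranged from 17835117 to 20753653. Counts were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test, with TMM scaling and genotype as the single term. Genes passed filterByExpr with a count minimum of 10 and a total of 15, which left 15385. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM values are TMM-scaled, SE is the log2 fold change divided by the root of its F statistic, and SD is over 3 libraries. Intervals of a fold are 1.96 SE on each side.

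The design, 37 gene lists, the naming rule and the alternatives were fixed before the data were examined. Lists were tested with limma 3.58.1 by camera with a preset correlation of 0.01, two-sided and adjusted over the lists. Camera with an estimated correlation and fry were run beside it, fry both for 1 shared direction and, as mixed fry, for changes in either direction. The naming rule took Rest, Srrm4 and Srrm3, then up to 12 higher and 12 lower called genes whose groups did not overlap, with predicted genes included where fewer than 12 others remained, then up to 4 members per list with the smallest adjusted p over that list, any list member called over all genes, and the sex-linked genes per library. It selected 166 genes. All 166 were recomputed under the alternatives. The text names part of the list members, mainly those of lists or genes that passed a test and those whose direction turned, and that choice was made after their values were seen. The values of 1 list member are not reported here.

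Alternatives were DESeq2 size factors or upper-quartile factors as scaling, DESeq2 1.42.0, limma-voom, limma on log2 of the deposited normalized values plus 1, no filter, a filter of CPM 1 in 3 libraries, an adjusted p under 0.10, the replicate number as a block, log2 CPM of Xist as a covariate, no genes of chromosomes X and Y, and each library left out. Leaving out chromosomes 1, 5 and 8, and leaving Tmem163 out of its list, were added after the data were seen. The pipeline was tested on simulated data for this comparison with 15108 genes tested. Of 50 genes changed at each size, edgeR called 30% at 1.5-fold, 64% at 2-fold, 86% at 3-fold and 98% at 4-fold, with 12 false calls among 151. The changed genes had a mean of at least 1 CPM, and each gene was drawn independently of the others. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9. Splicing of Rest and sequence variants need reads and were not analysed here.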

Results

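Gene expression was profiled in the embryonic neocortex of 3 WT and 3 Rest_het mice. Rest encodes a zinc-finger repressor of neuronal genes, and the mutant allele lacks exon 4, whose alternative use is the subject of the series. The WT libraries held 20753653, 20010687 and 19996943 gene reads and the Rest_het libraries 18426652, 17891118 and 17835117. The biological coefficient of variation was 0.183.

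The targeted gene came first. Rest (ENSMUSG00000029249) lies on chromosome 5 from 77265491 to 77286432 in GRCm38. It measured 20.6 CPM in WT and 18.1 CPM in Rest_het libraries (n = 3 each; exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). Its log2 fold change was -0.19 with an edgeR adjusted p of 0.49. The gene total covers all exons, so it does not check the deletion of exon 4 or the labels. Srrm4, a splicing factor of neurons that acts on Rest, measured 56.6 ± 5.97 CPM in WT and 53.9 ± 1.74 CPM in Rest_het libraries (SD, n = 3), with an edgeR adjusted p of 0.81. Its paralog Srrm3 measured 2.66 ± 0.125 and 3.31 ± 0.431 CPM (SD, n = 3), with an edgeR adjusted p of 0.56.

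The comparison of the genotypes asked which cortical genes differ between WT and Rest_het libraries. LacZ reads occurred only in WT and Cre-ERT2 reads only in Rest_het libraries, as described below. The groups thus differed in more than the Rest allele, and the called genes and lists cannot be credited to that allele alone. Of 15385 genes tested, 19 differed at an edgeR adjusted p under 0.05, 10 higher and 9 lower in Rest_het. In all 19 the 3 values of one group lay above those of the other, which 19.3% of tested genes showed against 10% by chance. Asb1, a SOCS-box protein, rose from 7.97 ± 0.604 to 599 ± 16.7 CPM (SD, n = 3), a log2 fold change of 6.23 with SE 0.10 and an edgeR adjusted p of 6.0e-08. Tmem163, a zinc transporter of vesicles, rose from 1.77 ± 0.120 to 85.3 ± 5.15 CPM (SD, n = 3), a log2 fold change of 5.58 with SE 0.11 and an edgeR adjusted p of 1.7e-07. Tgfbr3, the TGF-beta co-receptor betaglycan, was 17.4-fold higher, with an interval from 9.998 to 30.1. Traf3ip1, a protein of ciliary transport, was 3.67-fold higher and Git2, a regulator of Arf GTPases, 3.41-fold higher. Ing5, a reader of chromatin, was 2.21-fold higher and Tsn, which encodes the nucleic acid binding protein translin, 1.68-fold higher. The pseudogene Gm8730 was 10.6-fold higher.

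Among the genes that fell, Sall1, a transcription factor gene, dropped from 39.9 ± 2.42 to 19.2 ± 3.07 CPM (SD, n = 3), with an edgeR adjusted p of 0.026. Mn1, a transcriptional regulator, fell from 12456 ± 510 to 7544 ± 455 CPM (SD, n = 3), with an edgeR adjusted p of 0.030. It took 1.16 to 1.31% of WT gene reads. WT levels were 1.75-fold those of Rest_het for Irs1, an adaptor of the insulin receptor, 1.66-fold for Mgat5, an enzyme of N-glycan branching, and 1.67-fold for Farsa, a subunit of the phenylalanine tRNA synthetase. The zinc-finger genes Zkscan1 and Gm15446 were 1.65-fold and 2.01-fold higher in WT, and the pseudogene Tdpx-ps1 3.16-fold. Gm37100 had 0, 0 and 1 reads in WT against 27, 33 and 41, and Gm42980 had 0, 0 and 1 against 26, 26 and 39. Gm45293 had 74, 37 and 57 reads in WT against 1, 2 and 2. Gm8730 and Tdpx-ps1 are processed pseudogenes, whose reads are not safely told from those of similar genes, and Mgat5 and Tmem163 overlap on opposite strands in data without strand. The count of 19 became 12 without WT replicate 1, 35 without WT replicate 2 and 32 without Rest_het replicate 3, and DESeq2 called 131. Leaving out single libraries kept the call of 9 genes throughout and ended it for 10. It ended for Farsa without each of the 6 (edgeR adjusted p 0.055 to 0.10), for Mn1 without each but Rest_het replicate 2 (up to 0.18), for Sall1 (up to 0.12), Tsn (0.13) and Gm42980 (0.10) without each but Rest_het replicate 3, for Mgat5 without each but WT replicate 2 (0.13). It also ended for Irs1 (0.079) and Zkscan1 (0.070) without WT replicate 3 or Rest_het replicate 1, Irs1 in addition without Rest_het replicate 2, for Gm37100 without WT replicate 1 or 3 or Rest_het replicate 2 (0.079), and for Tgfbr3 without WT replicate 3 (0.071).

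**Figure D1:**
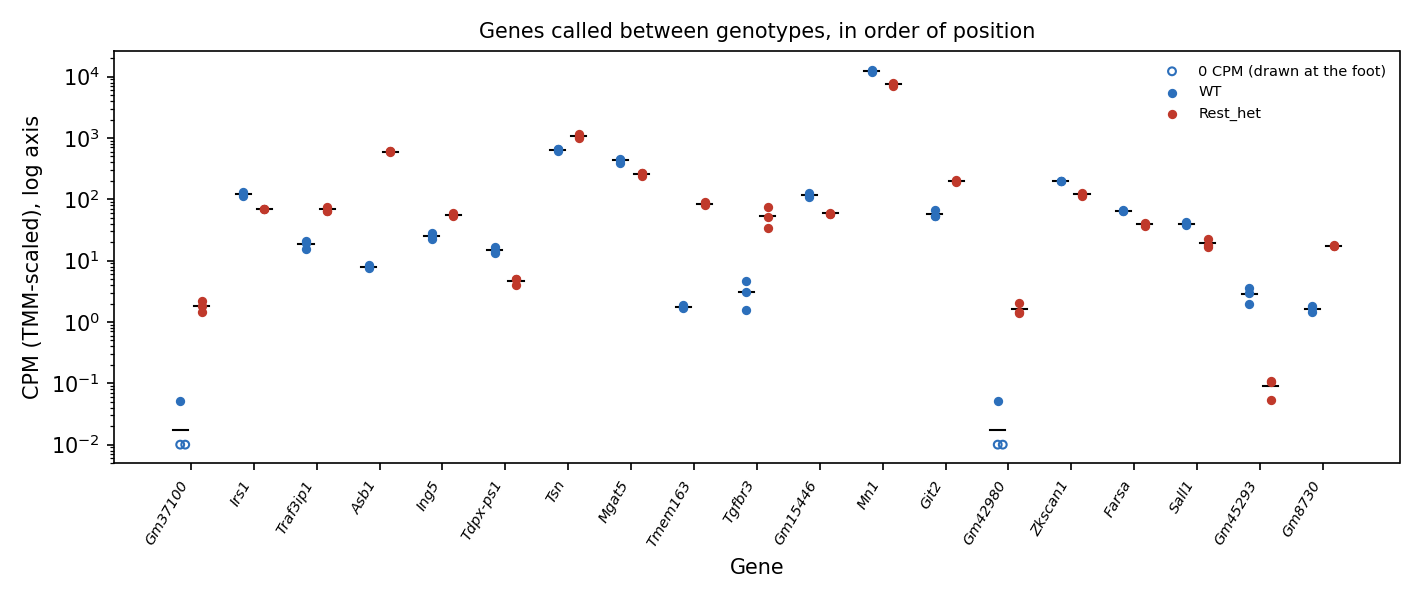
TMM-scaled CPM on a log axis for the 19 called genes, in order of chromosome and position. Blue points are the 3 WT libraries, red points the 3 Rest_het libraries, black lines the group means, and open circles mark 0 CPM. The groups are separated in each gene.

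The 19 genes called by edgeR all lie on chromosomes 1, 5 and 8, which hold 19.1% of tested genes with a position. There were 9 on chromosome 1 between 68115195 and 127679548, 6 on chromosome 5 between 107106570 and 138107822, and 4 on chromosome 8 between 84856989 and 102865798. In 10000 random sets of 19 tested genes, at most 14 fitted on any 3 chromosomes, which gives a p of 1e-04, the smallest these sets can give. Without chromosomes 1, 5 and 8, edgeR called 0 of 12449 genes, with 1396 at an unadjusted p under 0.05. Of the 131 genes DESeq2 called, 65 lie on the 3 chromosomes and 66 elsewhere. With no count filter 55 of the 107 genes edgeR called lie on them, with the Xist covariate 15 of 18, by limma on the deposited values 19 of 20, and at an adjusted p under 0.10 22 of 24. Without WT replicates 1, 2 and 3 in turn it was 12 of 12, 17 of 35 and 12 of 13, and without Rest_het replicates 1, 2 and 3 it was 11 of 17, 13 of 20 and 24 of 32. Rest itself lies 29.8 Mb from the nearest gene called by edgeR. Of the 39 other tested genes within 5 Mb of it, 0 were called by edgeR and 0 by DESeq2. An unadjusted edgeR p under 0.05 was reached by 7 of these 39, a larger share than the 1800 of all 15385 tested genes. So few genes do not settle whether the surroundings of Rest differ. The window leaves out Gabrg1, which DESeq2 called and which starts at 70751047 on chromosome 5. The list of genes next to Rest had a camera adjusted p of 0.97.

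**Figure D2:**
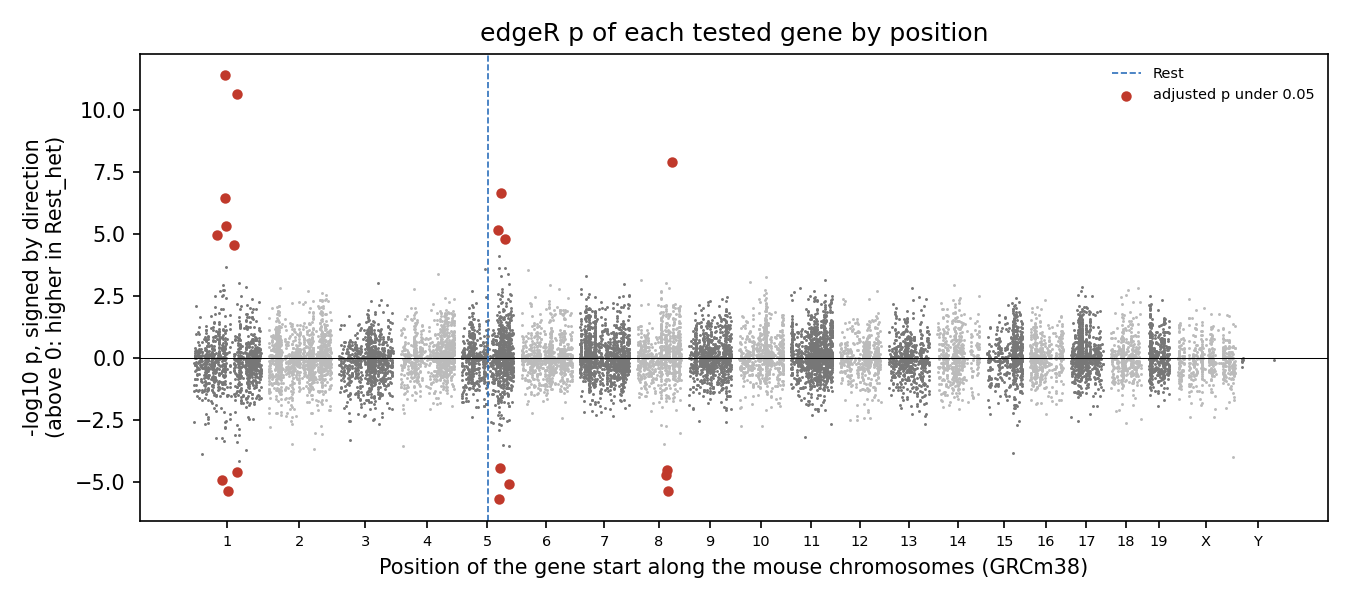
Position of each tested gene along the mouse chromosomes in GRCm38 against -log10 of its edgeR p, above 0 where the gene was higher in Rest_het and below 0 where it was lower. Red points are the 19 called genes, on chromosomes 1, 5 and 8, and the dashed line marks Rest.

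Known targets of REST were compared as a list, since the repressor acts on them directly. Of 54 tested members, 0 were called over all genes by edgeR, and DESeq2 called 3, all lower. At an unadjusted edgeR p under 0.05 there were 12 members, 10 lower and 2 higher. Of all 15385 tested genes 1800 reached it, 726 lower and 1074 higher. Adjusted over the list alone, 6 fell and 0 rose. Chgb, a granin of secretory granules, fell from 24.99 ± 2.93 to 13.9 ± 1.69 CPM (SD, n = 3; edgeR adjusted p over the list alone 0.012). Snap25, a SNARE protein of synaptic vesicle release, had a log2 fold change of -0.39 (edgeR adjusted p over the list alone 0.017), the cadherin Celsr3 -0.61 (0.035), the AMPA receptor subunit Gria2 -0.30 (0.0496) and the vesicle GTPase Rab3c -0.29 (0.0496). The list as a whole did not pass: camera gave it the direction lower with an adjusted p of 0.28, and an adjusted p of 0.92 with an estimated correlation, while 27 members lay below 0 and the median log2 fold change was 0.0045, of the other sign. Mixed fry, which tests for changes in either direction and does not compare the list with other genes, gave it an adjusted p of 0.00018. Its camera adjusted p was 0.029 without Rest_het replicate 2, and its direction turned, with 0.82, without Rest_het replicate 3. The number of members lower over the list alone was 0 without WT replicate 3, 1 without Rest_het replicate 1, 2 without WT replicate 2 and 3 without WT replicate 1. The list shares 21 members with 4 other neuronal lists.

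**Figure D3:**
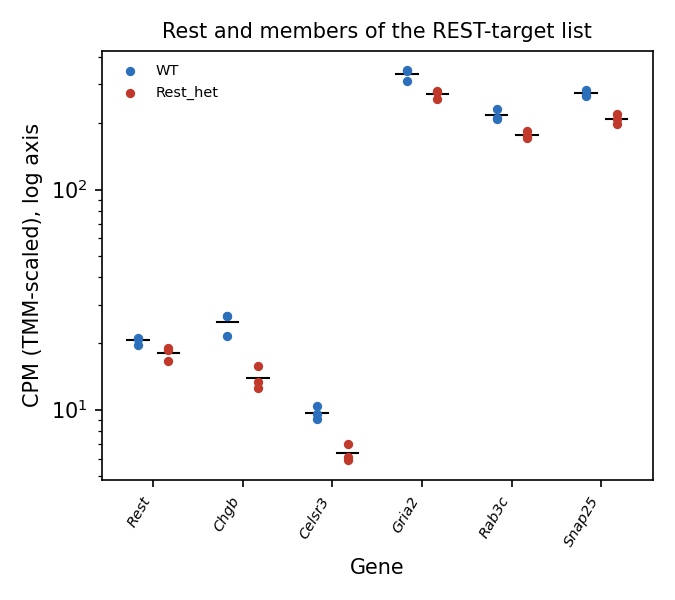
TMM-scaled CPM on a log axis for Rest and 5 of the 6 REST-target genes that passed over the list alone. Blue points are WT libraries, red points Rest_het libraries and black lines group means, with 3 libraries per group.

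Over the 37 lists, camera called 9, with 6 higher and 3 lower in Rest_het. With an estimated correlation 0 lists passed, the smallest adjusted p being 0.38, with 2 lists at an unadjusted p under 0.05, and directional fry called 0, with 5 at an unadjusted p under 0.05. Mixed fry, for changes in either direction, called 6: the REST-target, subplate, transmitter-receptor, stress-response, young-neuron and oligodendrocyte lists. Ribosomal protein genes were lower as a group, 54 of 59 below 0 with a median log2 fold change of -0.12 and a camera adjusted p of 0.00015, or 0.92 with an estimated correlation. None of them passed alone: Rpl10 measured -0.24 and Rpl3 -0.21 on the log2 scale. The 7 mitochondrially encoded genes were below 0 (camera adjusted p 0.031, or 0.92 with an estimated correlation), as were 16 of 20 upper-layer neuron genes (0.020, or 0.92 with an estimated correlation). Of the upper-layer genes, Plxna4, a semaphorin receptor, measured -0.36 and Mef2c, a transcription factor gene, -0.35, while Lmo4 measured 0.49.

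The stress-response list was higher, with 16 of 21 members above 0 (camera adjusted p 0.0095, or 0.73 with an estimated correlation). Over the list alone 3 members rose: the endoplasmic reticulum genes Herpud1 by a log2 fold change of 0.40 and Hspa5 by 0.37 (edgeR adjusted p over the list alone 0.016 each), and the amino acid transporter gene Slc3a2 by 0.29 (0.045). Herpud1 lies inside the span of called genes on chromosome 8, while Hspa5 and Slc3a2 lie on chromosomes 2 and 19. The p53-response list was higher (0.035, or 0.89 with an estimated correlation), with Plk2 at 0.32. The oligodendrocyte-lineage list was higher (0.016, or 0.73 with an estimated correlation), and Cnp, a myelin enzyme, rose by 0.61 (edgeR adjusted p over the list alone 0.0069). The subplate and Cajal-Retzius list was higher (1.1e-05, or 0.38 with an estimated correlation), with Tmem163 its 1 called gene, and its adjusted p was 0.68 without Tmem163. The list of hippocampus, cortical hem and choroid plexus genes was higher (0.0018, or 0.89 with an estimated correlation). Otx2 and Prox1, both transcription factor genes, rose over that list alone (edgeR adjusted p 0.042 each), and Ttr, the main transcript of the choroid plexus, measured 2.27 and 3.09 CPM in WT replicates 2 and 3 and 53 CPM in replicate 1, against 169, 5.49 and 357 CPM in Rest_het libraries. The thalamus and hypothalamus list was higher (0.031, or 0.73 with an estimated correlation). Its members Prox1, Lhx9, Barhl2 and Calb2 rose over the list alone, by log2 fold changes of 1.45, 1.05, 1.84 and 0.77 (edgeR adjusted p over the list alone 0.024 each). Rest_het replicate 2 was the highest for Barhl2 (2.70, 10.9 and 4.09 CPM in the mutants), Lhx9 (10.9, 14.4 and 6.16) and Prox1 (2.70, 4.38 and 1.70). It was the highest of all libraries too for Isl1, a marker of the ventral telencephalon, with 41.9 CPM against 19.2 and 18.9 in the other mutants, and for the interneuron gene Sst, with 12.4 CPM against 3.89 and 4.67. Calb2 was highest in Rest_het replicate 1 instead (26.3, 17.2 and 14.7 CPM in the mutants). Prox1, Lhx9, Barhl2 and Calb2 lie on chromosomes 1, 5 and 8, without which the list's direction turned, with a camera adjusted p of 0.94. Leaving these chromosomes out removes every member that rose over the list alone, so the turn does not tie the list to the called genes. All of these members lie outside the spans of the called genes on those chromosomes. Barhl2, which DESeq2 called, ends at 106458166 on chromosome 5, close to the span that starts at 107106570. The outermost called genes set the spans, so a place outside them does not exclude a shared regional effect. Camera called 5 lists without WT replicate 2 and 16 without Rest_het replicate 3, against 9 with all 6 libraries.

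Some list calls rested on single libraries. Without WT replicate 2 the camera adjusted p was 0.27 for the oligodendrocyte, 0.14 for the upper-layer, 0.24 for the mitochondrial, 0.089 for the thalamus and 0.14 for the p53 list. Without Rest_het replicate 2 it was 0.11 for the oligodendrocyte, 0.15 for the upper-layer and 0.079 for the mitochondrial list. Without Rest_het replicate 1 it was 0.077 for the mitochondrial, 0.073 for the thalamus and 0.19 for the p53 list. Without WT replicate 3 the thalamus list had 0.31, and without WT replicate 1 the p53 list had 0.090.

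The other 27 lists besides the REST targets did not pass, 28 in all. Of the progenitor and neuron lists, camera gave adjusted p of 0.64 for apical progenitors, 0.39 for intermediate progenitors, 0.22 for young neurons, 0.705 for deep layers, 0.28 for interneurons and 0.36 for ventral telencephalon. In the young-neuron list Map2, a dendritic microtubule protein, fell by 0.60 on the log2 scale (edgeR adjusted p over the list alone 0.014). Map2 ends at 66442583 on chromosome 1, close to the span of called genes that starts at 68115195. REST cofactors had 0.91, neural splicing factors 0.47, synaptic vesicle genes 0.55, ion channels 0.30 and hair-cell genes 0.74. Proliferation lists had 0.64 for S phase and 0.079 for G2 and M phase, and replication-dependent histones 0.52. Markers of other cells had 0.22 for erythroid cells, 0.47 for the endothelium and mural cells, 0.64 for meninges and 0.91 for microglia. Immediate early genes had 0.96, hypoxia and glycolysis 0.28, heat shock 0.52, sterol synthesis 0.096, interferon response 0.59 and nuclear genes of oxidative phosphorylation 0.705.

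Some of these lists passed camera when 1 library was left out. Without WT replicate 1 the adjusted p was 0.019 for ventral telencephalon, 0.00084 for the endothelium and mural cells, 0.00018 for meninges and 0.010 for G2 and M phase. Ventral telencephalon had 0.0080 without WT replicate 3 and 0.022 without Rest_het replicate 1, and sterol synthesis 0.036 without WT replicate 2. Without Rest_het replicate 2 it was 0.037 for young neurons, 0.0079 for the endothelium and mural cells and 0.0081 for meninges, while the directions of the ventral telencephalon and interneuron lists turned, with 0.93 and 0.47. Without Rest_het replicate 3 it was 0.012 for ventral telencephalon, 0.020 for interneurons, 0.0038 for erythroid cells, 0.029 for transmitter receptors, 0.011 for G2 and M phase, 0.020 for sterol synthesis and 0.045 for the interferon response.

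The presence of Xist and of Y-linked reads was balanced between the groups. Xist, the X-inactivation RNA, had 764 reads in WT replicate 2 and 778 in Rest_het replicate 3, and 0 or 1 in the other 4 libraries. The Y-linked gene Ddx3y had 1828 and 1344 reads in WT replicates 1 and 3 and 1230 and 1182 in Rest_het replicates 1 and 2, against 2 and 0 in the libraries with Xist. Levels in the libraries with Y-linked reads were less even. Without TMM scaling, Uty measured 90.0 and 86.8 CPM in WT against 69.0 and 66.1 CPM in Rest_het. Eif2s3y measured 40.1 and 39.4 against 25.9 and 31.3 CPM, while Kdm5d overlapped, with 17.2 and 14.7 against 16.2 and 12.8 CPM. All 4 tested members of the sex-linked list lay below 0, with a median log2 fold change of -0.33 and a camera adjusted p of 0.74.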

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

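The tests here address patterns already seen in the results. The predictions for extra copies and for medial cortex cells were written before those tests were run. The other predictions were written after the values were seen. A signal in data outside the gene counts drew attention: 121 LacZ reads in the 3 WT libraries and 43 Cre-ERT2 reads in the 3 Rest_het libraries. LacZ had 27, 51 and 43 reads in WT and 0 in each Rest_het library, where the floor of 3 reads per library lay at 0.163 to 0.168 CPM without TMM scaling. Cre-ERT2 had 10, 16 and 17 reads in Rest_het and 0 in each WT library.

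For this transgene split, contaminating reads that enter all libraries alike would give 107.8 LacZ reads in the mutants, or 70.5 at the lowest rate of a WT library, where 0 were seen, which argues against it. Reads of the mouse Esr1 gene assigned to the Cre-ERT2 sequence would give 14.8 reads in WT, or 9.88 at the lowest ratio of a mutant library, where 0 were seen although Esr1 had 21 reads there and 61 in the mutants. PCR copies are among these reads, so the number of independent molecules is not known. Transgenes carried by the embryos that differ between the groups may account for it. In 6 of 6 libraries there were more than 3 reads of 1 transgene and 0 of the other. That count restates the split, so it does not favour carried transgenes over other sources that follow the groups. Contamination that followed the order or day of preparation cannot be told apart from carried transgenes, because the labels give 0 preparation batches.

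Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, called as many as 19 genes, and the highest other split called 13. That other split set WT replicate 1 and Rest_het replicates 2 and 3 against the other libraries. Between pairs of libraries, the chi-square of gene counts per degree of freedom was 23.8 to 54.8 inside either set and 78.5 to 118 across. So this split follows a difference between libraries that crosses the genotypes and was not modelled, and it is no plain reference for chance. The splits are too few for a share under 0.05. The 19 called genes sit on 3 chromosomes, and a genome-wide response to the Rest allele as their whole source is argued against by the 19 of 19 on them, where random sets reached at most 14 (permutation p = 1e-04, the smallest they can give), although DESeq2 also called 66 genes elsewhere and edgeR with no count filter had 55 of 107 on them. Extra or missing copies of whole stretches are argued against too, since the stretch median farthest from 0 was a log2 fold change of 0.053. The medians are over 229, 420 and 110 tested genes on chromosomes 1, 5 and 8, so copy changes of smaller parts stay open. Chromosome stretches of another strain origin that differ between the groups may contribute: 18.4% of the 740 uncalled genes inside the stretches had an unadjusted p under 0.05 against 11.3% elsewhere (permutation p = 0.015 by circular shifts), with 19.1% each on chromosomes 1 and 5. On chromosome 8 it was 14.2%, close to the 12.9% of the same chromosomes outside the stretches. The called genes of this same comparison set the stretch ends, while the shifted places were not chosen that way. Low p values that cluster for any reason would raise the share inside. The circular-shift p can therefore be too small, and it does not favour strain origin over other regional effects. Variants were not examined, so a regional effect of another kind stays open.

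The higher hippocampus, hem and choroid plexus list may reflect uneven carry-over of choroid plexus between dissections. Within the groups its 6 tested choroid plexus genes varied together, with a median correlation of 0.943 against at most 0.841 in 10000 random sets of genes of like level (permutation p = 1e-04, the smallest they can give). The sets were not matched for spread between libraries. Any uneven amount of choroid plexus would give such joint variation, so it does not single out the dissection. Otx2 alone of the 6 had separated groups, at 0.86 CPM in WT replicate 1 and 1.27 CPM in Rest_het replicate 2. Ttr measured 53 and 5.49 CPM in these libraries. An uneven amount of choroid plexus in the embryos themselves stays open. A change in cells of the medial cortex in all mutants stays open: 1 of the 9 other members, Prox1, had separated groups against 19.3% of tested genes (exact binomial p = 1), and with 9 members even 0 would give an exact p of 0.22. These 9 had a median log2 fold change of 0.20 against 1.84 for the choroid plexus genes, and Zic1, at 1.36, rested on 17.9 CPM in Rest_het replicate 1 against 4.54 and 7.06 in the others.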

How the results depend on the processing

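All alternatives were fixed before the data were examined, except leaving out chromosomes 1, 5 and 8 and leaving out Tmem163. The number of genes called, 19 with 10 higher and 9 lower, stayed within 1.5 times under both other scalings, limma-voom, limma on the deposited values, the CPM filter, the Xist covariate and without chromosomes X and Y. DESeq2 called 131 (74 higher, 57 lower) and no filter gave 107 (61 and 46), both with the 19 among them. Leaving out 1 library gave 12 to 35, with 7 to 21 higher and 4 to 15 lower. Without chromosomes 1, 5 and 8 edgeR called 0 (0 higher, 0 lower), with 1396 at an unadjusted p under 0.05, since the called genes were removed, while DESeq2 had called 66 there. Asb1, Tmem163, Gm8730, Git2 and Traf3ip1 passed in all 16 alternatives, Mn1 and Farsa in 8, Mgat5 and Tsn in 9, Sall1 and Gm42980 in 10, and the other 8 in 12 to 15. Rest stayed between -0.22 and -0.14 and never passed. Scaling moved the median of all genes by under 0.1.

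Same-numbered libraries did not pair: their deviations correlated at 0.011, 0.037 and -0.14. With the replicate block edgeR called 6 of the 19 genes, 6 higher and 0 lower, with 571 lower at an unadjusted p under 0.05.

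The 9 called lists became 0 with an estimated correlation and 0 by directional fry, 6 by mixed fry, and 5 to 16 with 1 library left out. The REST-target list ranged from 0.029 to 0.82 in adjusted p with 1 library left out, its direction turning without Rest_het replicate 3. The cause was not tested. The thalamus list turned without chromosomes 1, 5 and 8 (0.94), a step that removes the 4 members that rose over the list alone. Lists not called also turned in direction when single libraries were left out, with adjusted p from 0.61 to 0.96 for REST cofactors, 0.36 to 0.99 for apical progenitors, 0.54 to 0.99 for deep layers, 0.020 to 0.57 for interneurons, 0.0080 to 0.93 for ventral telencephalon, 0.0038 to 0.56 for erythroid cells, 0.00084 to 0.58 for the endothelium and mural cells, 0.00018 to 0.90 for meninges, 0.083 to 0.85 for microglia, 0.15 to 0.98 for synaptic vesicles, 0.029 to 0.64 for transmitter receptors, 0.12 to 0.98 for S phase, 0.78 to 0.88 for immediate early genes, 0.045 to 0.89 for the interferon response, 0.38 to 0.93 for nuclear oxidative phosphorylation, 0.49 to 0.96 for hair cells, 0.57 to 0.99 for genes next to Rest and 0.12 to 0.95 for sex-linked genes. Turned too were hair cells with no filter (0.95), immediate early genes with the CPM filter (0.90), REST cofactors by fry (0.88), immediate early (0.96), Rest-neighbour (0.99) and sex-linked genes (0.36) with the Xist covariate, and REST cofactors (0.98), transmitter receptors (0.87) and hair cells (0.98) without chromosomes 1, 5 and 8. Genes that turned were far from the threshold. With 1 library left out, log2 fold changes ran from -0.14 to 0.0090 for Srrm4, -0.90 to 0.24 for Foxc1, -0.063 to 0.80 for Oasl2, -0.012 to 0.44 for Hist1h2bc, -0.14 to 0.41 for Hist1h1e, -1.09 to 0.085 for Eif2s3y, -0.997 to 0.17 for Uty, -0.83 to 0.34 for Ddx3y and -0.77 to 0.42 for Kdm5d. The Xist covariate gave 0.42 for Eif2s3y, 0.66 for Uty, 0.70 for Ddx3y and 0.75 for Kdm5d. Of the recomputed values of single genes, 2654 kept their direction and side, 58 lost a call and 21 gained one. At this depth and number the simulation recovered 30% of 1.5-fold changes, so changes of that size can be missed. The simulation held no variation shared between genes, so recovery in the data may be lower.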

Other observations

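The values here were singled out after they were seen, apart from the list of transmitter receptors. That list did not pass for 1 shared direction (camera adjusted p 0.50) and passed mixed fry, for changes in either direction (adjusted p 0.00073), and 7 of its 33 members passed over the list alone, in both directions. Glra2, a glycine receptor subunit, fell by 1.07 on the log2 scale, as did Gria2 by 0.30. Gabrg1, Gabrb1, Gabra5 and the metabotropic glutamate receptor gene Grm7 rose, by 2.37, 1.08, 0.85 and 2.12. Each of these genes that rose was highest in Rest_het replicate 2, Grm7 by more (1.03, 2.83 and 1.49 CPM in the mutants) than Gabrb1 (4.22, 4.43 and 2.66). Without that library the list's direction turned to lower (camera adjusted p 0.64). None of the 7 passed over all genes by edgeR, where Glra2 had the smallest adjusted p of 0.075, and all 7 had an unadjusted p under 0.05. Glra2, Gabrg1 and Grm7 were among the genes called by DESeq2. The largest rises started from low levels: WT libraries held 0.29, 0.42 and 0.36 CPM of Gabrg1 and 0.48, 0.37 and 0.36 CPM of Grm7. Gabrg1 and Gabrb1 lie close together on chromosome 5, which also holds Rest, with starts at 70751047 and 71658113. Their rises therefore may not be separate events, and a regional effect on this pair was not tested.

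Rgs5, a marker of pericytes on chromosome 1, measured 216, 152 and 181 CPM in WT against 1432, 1161 and 196 CPM in Rest_het libraries, so 2 of 3 mutants stood apart. Its edgeR adjusted p was 0.32. Pdgfrb, another pericyte gene, measured 8.55, 4.17 and 6.75 against 9.13, 6.37 and 9.56 CPM (log2 fold change 0.36), and the pericyte genes Kcnj8, Vtn and Abcc9 had log2 fold changes of 0.13, -0.077 and -0.22. The mural-cell genes Cspg4 and Notch3 each had 0.33, with separated groups for Cspg4. Wdfy1, inside the stretch of chromosome 1 that holds called genes, measured 178, 98.5 and 99.9 CPM in WT against 175, 108 and 97.3 CPM in Rest_het, with 1 high library in each group.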
